A study of Mus musculus with 3 samples.

How the data were processed

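RNA was profiled from cells of mouse dorsal root ganglia, the sensory ganglia beside the spinal cord, at embryonic day 14.5. Per the labels, ganglia from spinal levels T11 to S1 of C57BL/6 embryos carrying a Ret-EGFP reporter were dissociated and sorted for fluorescence, and RNA was pooled per library. The 3 libraries, named A, B and D as in the labels, form 1 group. Library A was made from 100 ganglia of 5 embryos (3 male, 2 female), library B from 100 ganglia of 6 embryos (2 male, 4 female) and library D from 80 ganglia of 4 embryos (3 male, 1 female), per the labels. The series description calls the reporter a knock-in at the Ret locus in heterozygotes, while the genotype label writes it as a transgene. Per the labels' protocols, 10 ng of total RNA was reverse transcribed and amplified with the SMARTer Ultra Low Input kit, the cDNA was sheared, and libraries were amplified for 12 PCR cycles. No molecular identifiers are described, so repeated reads of 1 molecule cannot be told from separate molecules, and intervals and floors given here cover counting error only.

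The authors deposited whole-number counts per Ensembl gene, 1 file per library, with exon coordinates and gene lengths. Per the submitters' processing notes, Subread and featureCounts 1.4.5 were used with genome build GRCm38.p2. Their settings, including the use of strand and the treatment of reads with several matches, are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies were therefore treated as not separable. The authors also deposited CPM, which equalled the count scaled to the library's total count for every gene (largest difference 4.7e-11). RPKM was deposited as well, and equalled that CPM divided by the gene length in kilobases (largest difference 2.7e-11). Coordinates are 1-based, as in the deposited files, and span each gene's first to last exon.

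Total counts were 20181558 in library A, 20355302 in library B and 29061086 in library D. The files list 41388 genes, of which 40254 matched a symbol in GENCODE M21. The other 1134 kept their identifiers. All deposited genes entered the totals. TPM was computed from the counts and the deposited lengths. A count of 0 was read as allowing up to 3 counts. Levels of different genes were compared as TPM within a library, because a raw count grows with gene length.

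Lists of genes were fixed before the data were examined: 26 lists holding 316 genes, for sensory neurons and their subtypes, receptors, ligands and channels, other cell types that dissected ganglia could hold, cell cycle, stress, sex and Hox genes. All listed genes were found, 1 of them through a RefSeq synonym (Drgx as Prrxl1). A list's level was the median TPM of its members per library, given as mean ± SD over 3 libraries. Its mean log2(TPM + 0.1) was set against 10000 random lists of the same size. Ratios between 2 lists, and between the 2 genes of 13 pairs, were taken within each library and tested with a two-sided exact sign-flip permutation test, whose smallest p with 3 libraries is 0.25. No such test can pass 0.05. A pair needed at least 10 counts of both genes in every library, which 11 pairs had. No comparison between groups was possible with 1 group.

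Variation between the libraries was tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr, an intercept-only negative binomial fit with trended dispersion, and a deviance goodness-of-fit test per gene (chi-square with 2 degrees of freedom), with Benjamini-Hochberg adjustment at 0.05. The quasi-likelihood test needs 2 groups and was not used. The test asks which genes differ between libraries by more than other genes of their level. It was tested on simulated data with the real means and library sizes, in which 13842 genes passed the filter. Recovered were 1.49% of 67 genes changed 2-fold in a library, 25.4% of 67 changed 4-fold and 86.4% of 66 changed 8-fold. Among 76 calls, 1 was false. Every simulated gene had the same coefficient of variation (30.3%), and changed genes were drawn from those with a mean CPM of at least 10. Real genes may differ in their variation, so these rates, and the false call rate above all, may not hold for them. For each list, the median over members of log2 CPM (prior count 2) in a library minus the mean of the other 2 was set against 10000 random lists, each member replaced by a gene within 100 ranks of its mean level. These percentiles describe the libraries and are not p-values. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

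The alternatives tried were other expression thresholds, thinning to the smallest library, CPM in place of TPM, totals without mitochondrial and hemoglobin genes, lists limited to members of at least 1 TPM, other summaries and pseudocounts, other filters, normalisations and dispersions, DESeq2 1.42.0 dispersion outliers, and leaving out each library. Removal of trends with GC content and gene length, and list shifts against each other library alone, were added after the data were seen. The correction of the GC trend for genes low in library B was also chosen after its outcome had been seen. Lists of nuclear-retained RNAs and of progenitor and newborn neuron genes were written later, once the varying genes were known and before the lists' own values were computed. Genes named in the text follow a rule fixed beforehand. It takes all members of the receptor, ligand, sex and Hox lists and of the gene pairs, the 6 highest and 3 lowest members of every other list, the 15 highest nuclear coding genes apart from ribosomal protein genes, and all members of lists that stood apart in a library. Among varying genes with a mean CPM of at least 10, the rule takes the 15 with the largest range and the 5 highest and 5 lowest per library. Expression of the EGFP reporter itself was not analysed here, and results for some single genes of the lists are not reported here.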

Results

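The series measured which genes are expressed in the Ret-positive cells of mouse dorsal root ganglia at embryonic day 14.5, when sensory neurons are extending axons and beginning to separate into subtypes. Ret encodes the receptor tyrosine kinase for ligands of the GDNF family. Cells were sorted by a Ret-EGFP reporter from ganglia of levels T11 to S1, and 3 pooled libraries (A, B and D) were sequenced, with no control population. Their total counts were 20181558, 20355302 and 29061086. Each value below is a mean over the 3 libraries ± SD (n = 3) unless a single library is named. Each label gives a pool of several embryos, so the SD covers differences between pools as well as technical noise. Across genes, the Pearson correlation of log2 CPM was 0.979 between A and B, 0.965 between A and D and 0.966 between B and D. Genes are not independent replicates, so these values describe the libraries only. Counts of the closest pair, A and B, still differed by 48.6 times the variance that counting error gives, so no library was a copy of another.

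The cells expressed 13897 genes at a mean of at least 1 TPM, of which 11877 were protein coding. Among nuclear coding genes apart from ribosomal protein genes, Tuba1a, an alpha-tubulin of growing neurons, reached 17626 ± 1281 TPM, and Tubb3, the neuronal beta-tubulin, 14755 ± 2579 TPM. Sncg, which encodes gamma-synuclein, stood at 16880 ± 3071 TPM and the actin-binding gene Tmsb4x at 14063 ± 4815 TPM. Selenow, which encodes a selenoprotein, reached 8498 ± 1989 TPM. Stmn2 (8246 ± 1230 TPM) and Gap43 (8143 ± 167 TPM), both linked to axon growth, were also among the 15 highest, as were Actb, Calm2, Stmn3, Nefl, Tubb5, Dpysl2, Ndufa4 and Hsp90ab1. The 50 highest genes of each library took 18.1% of counts in A, 17.8% in B and 22.0% in D. Mitochondrial genes took 1.72%, 1.14% and 2.75%.

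The first question was how far the sorted population is neuronal. Sensory neuron genes stood above the lists of all 9 other cell types in every library. Their median was 137 ± 18.7 TPM, 26 of 27 members reached 1 TPM and 16 reached 100 TPM. Besides Tubb3, Stmn2 and Gap43, the highest members were Nefl (4934 ± 1588 TPM) and Nefm (1502 ± 400 TPM), which encode neurofilaments, and Uchl1 (2691 ± 412 TPM). Among the lowest were Tlx3 (2.29 TPM on average) and Eya2, which stayed at 0.317 ± 0.120 TPM. Schwann and satellite glia genes had a median of 7.55 ± 3.16 TPM, 19.0-fold below the neuronal list (log2 ratio 4.25 ± 0.50). This list was uneven: S100b (343 ± 92.5 TPM), Fabp7 (310 ± 109 TPM), Ednrb (82.2 ± 17.2 TPM) and Pmp22 (73.9 ± 28.7 TPM) were well expressed, whereas Dhh, Foxd3 and Gfap stayed below 1 TPM.

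Most markers of other tissues lay lower still. Of the sympathetic list's 12 genes, Th is also in a sensory neuron list. The neuronal median exceeded that of mesenchyme and pericyte genes 47.8-fold (log2 ratio 5.58 ± 0.78), of macrophage genes 132-fold (7.04 ± 0.51), of sympathetic neuron genes 211-fold (7.72 ± 0.57), of endothelial genes 354-fold (8.47 ± 0.65) and of cartilage genes 715-fold (9.48 ± 0.56). For skeletal muscle the log2 ratio was 11.41 ± 1.17 (10.75 without A), from a muscle median of 0.0573 ± 0.0310 TPM. The spinal cord list averaged 0.0235 ± 0.0217 TPM; its median gene had no counts in A, and the log2 ratio was 11.69 in B and 12.04 in D. Within the spinal cord list the choline transporter gene Slc5a7 reached 6.13 ± 2.73 TPM, while Mnx1, Lbx1 and Olig2 had no counts. Erythroid genes had a median of 13.9 ± 8.76 TPM and a log2 ratio of 3.47 ± 1.05, which was 4.06 without library D. They lay closer than glia in A and D but not in B (4.31 against 3.67 for glia), nor as CPM (6.54 against 5.04). Every ratio computed in all 3 libraries was positive in 3 of 3, with an exact sign-flip p of 0.25, the smallest that 3 libraries allow. Against 10000 random lists of the same size, the mean log2 level of the sensory neuron list stood at percentile 100. Glial genes stood at percentile 97.2, erythroid genes at 85.2 and mesenchyme and pericyte genes at 64.5, so these lay above most random lists. Macrophage genes stood at 29.4, sympathetic neuron genes at 23.4, endothelial genes at 2.32, cartilage genes at 0.96, skeletal muscle genes at 0.51 and spinal cord genes at 0. The folds to the other lists depended on how a list was summarised: restricted to members of at least 1 TPM, the log2 ratio was 3.03 for glia, 3.18 for sympathetic neurons and 3.43 for muscle.

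**Figure D1:**
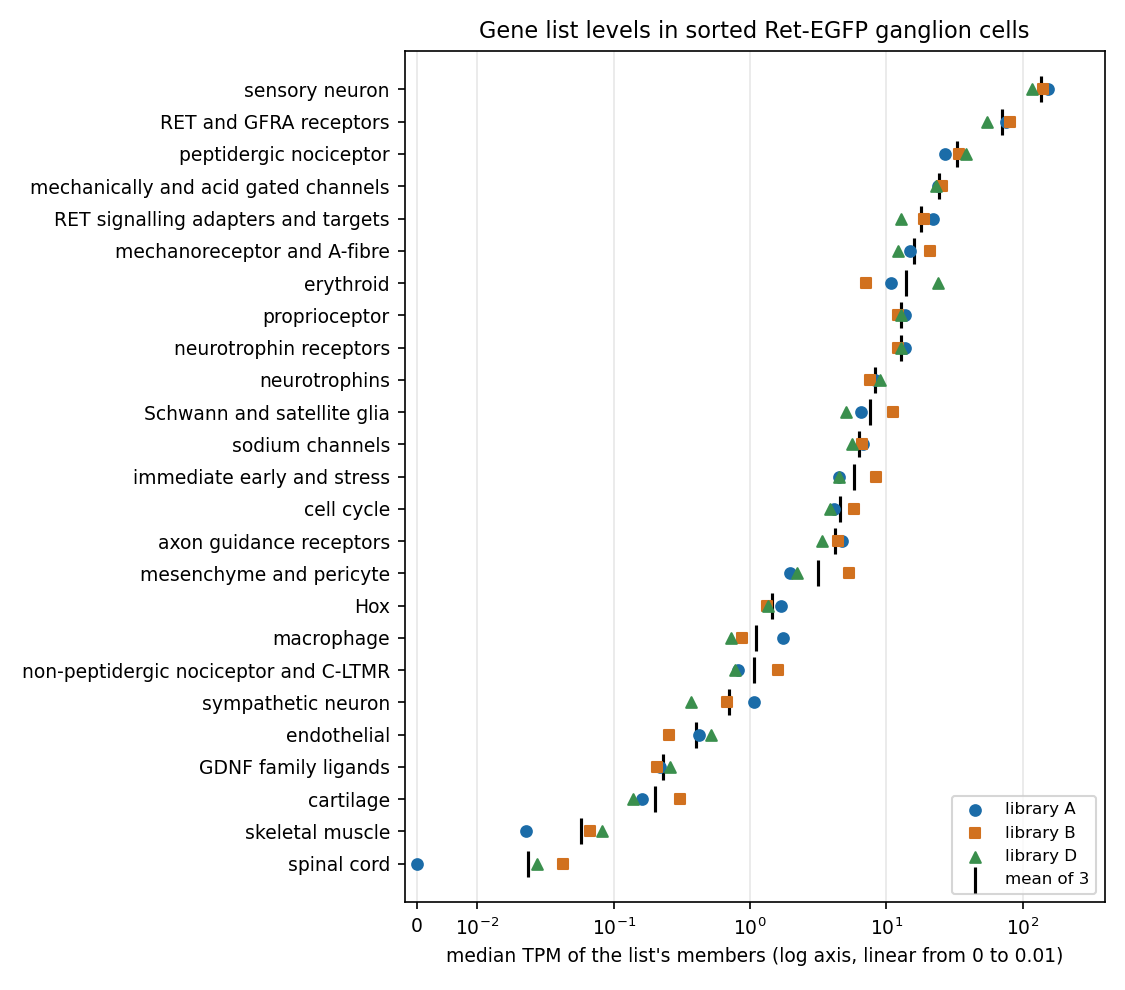
Median TPM of the members of 25 gene lists (x axis, log scale, linear below 0.01) in libraries A, B and D (symbols), with the mean of the 3 as a black bar. Sensory neuron genes were highest in every library, at 153, 141 and 116 TPM, and the spinal cord median was 0 in A.

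The second question concerned the receptors for GDNF family ligands, in which RET signals together with a GFRA co-receptor. Of the 6 receptor genes, 5 reached 1 TPM, with a list median of 70.2 ± 13.6 TPM. Gfra3 (ENSMUSG00000024366, chromosome 18, 34689903 to 34720387, GRCm38.p2), the co-receptor for artemin, was the highest at 363 ± 84.1 TPM. Gfra2 (chromosome 14, 70890130 to 70979838), for neurturin, followed at 85.6 ± 25.8 TPM and Gfra1 (chromosome 19, 58235604 to 58455909), for GDNF, at 81.4 ± 24.7 TPM. Ret itself (ENSMUSG00000030110, chromosome 6, 118151748 to 118197744) stood at 59.8 ± 10.7 TPM, from 2872, 4207 and 5319 counts. Cells were sorted on a reporter of this gene, so its presence describes the gate. The sources differ on whether the reporter was knocked into the Ret locus in heterozygotes. Whether every Ret allele was intact is therefore not known, for this level and for the ratios of Ret given below. Gfra4 reached 3.54 ± 1.16 TPM. Gfral, the receptor for GDF15, had no counts in any library, which allows up to 0.149, 0.147 and 0.103 CPM.

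Within libraries, Gfra3 exceeded Gfra2 4.32-fold (log2 Gfra2/Gfra3 -2.11 ± 0.22), Gfra1 4.54-fold (log2 Gfra1/Gfra3 -2.18 ± 0.29) and Ret 6.02-fold (log2 Ret/Gfra3 -2.59 ± 0.25), in 3 of 3 libraries each (exact sign-flip p = 0.25). Gfra1 and Gfra2 differed by less than the spread between libraries (log2 ratio -0.07 ± 0.12, exact p = 0.5). Ret also lay within 1 SD of equality with Gfra1 (-0.41 ± 0.52, exact p = 0.5) and slightly beyond it with Gfra2 (-0.48 ± 0.47, exact p = 0.5). These ratios rest on the correction for gene length, from 1992 bases for Gfra3 to 7341 for Ret. As CPM, without it, the log2 ratio to Gfra3 was -1.31 for Gfra2, -0.72 for Gfra1 and -0.71 for Ret, that of Gfra1 to Gfra2 was 0.59 and that of Ret to Gfra2 0.60. The ligands themselves were scarce in the sorted cells, with a list median of 0.228 ± 0.0253 TPM: Pspn reached 1.90 ± 1.11 TPM, and Nrtn, Artn, Gdnf and Gdf15 each stayed below 1 TPM, with at most 8 counts in any library.

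Of the adapters and targets of RET signalling, 19 of 21 reached 1 TPM and the median was 18.0 ± 4.69 TPM. The adapter genes Dok4 (270 ± 103 TPM), Dok5 (146 ± 2.89 TPM) and Grb2 (98.4 ± 9.91 TPM) led, followed by the feedback inhibitor Spry2 (76.1 ± 11.4 TPM), the transcription factor Etv1 (49.3 ± 9.93 TPM) and the phosphatase Dusp6 (43.9 ± 12.2 TPM). Dok6 and Spry1 averaged below 1 TPM.

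Neurotrophin receptors were compared next, since they divide early sensory neurons into classes. All 5 receptor genes were expressed (list median 12.9 ± 0.798 TPM). Ntrk3, the NT-3 receptor, stood at 12.9 ± 0.798 TPM and Ntrk2, the BDNF receptor, at 9.51 ± 2.07 TPM. Ret was 6.33-fold above Ntrk2 (log2 2.66 ± 0.24) and 4.60-fold above Ntrk3 (log2 2.20 ± 0.33), in 3 of 3 libraries each (exact p = 0.25). Ntrk2 was below Ntrk3 in all 3 libraries (log2 -0.46 ± 0.36, exact p = 0.25). As CPM, without length correction, the order of Ntrk2 and Ntrk3 turned (log2 0.94), and the log2 ratio of Ret was 1.75 to Ntrk2 and 2.69 to Ntrk3. Ngfr, the shared p75 receptor, was high but uneven, at 1785 TPM in A, 557 in B and 453 in D. Among the 4 neurotrophins (list median 8.30 ± 0.707 TPM), Ntf3 (27.5 ± 1.71 TPM) and Bdnf (16.4 ± 1.51 TPM) were expressed, whereas Ntf5 stayed below 1 TPM.

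**Figure D2:**
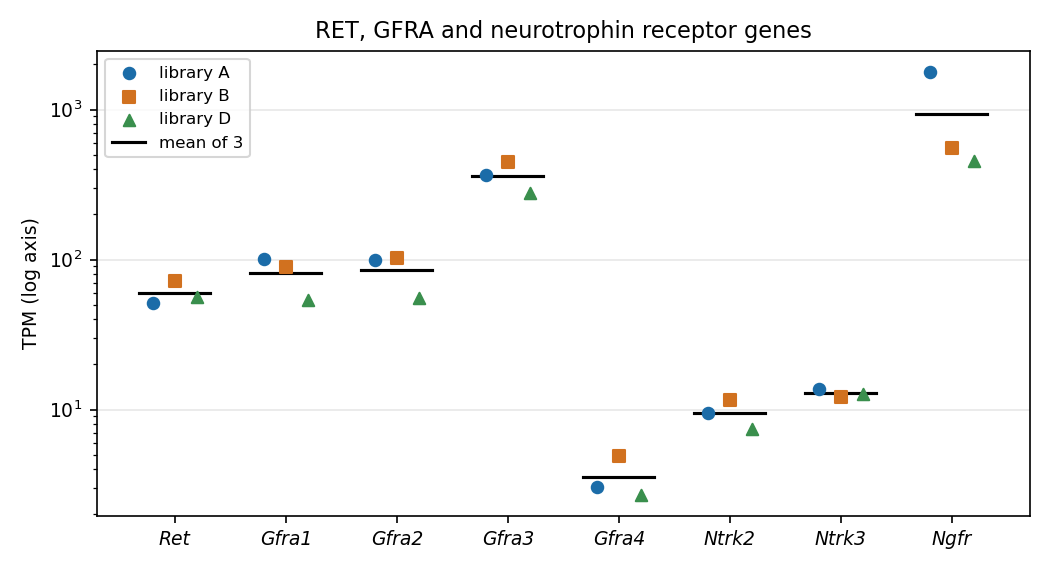
TPM (y axis, log scale) of Ret, the GFRA co-receptors, Ntrk2, Ntrk3 and Ngfr in libraries A, B and D (symbols), with the mean of the 3 as a black line. Gfra3 lay above Gfra1, Gfra2 and Ret in every library, and Ntrk2 lay below Ntrk3. Gfral, with no counts, is not drawn.

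All 8 peptidergic nociceptor genes were expressed, with a list median of 33.1 ± 5.66 TPM. The neuropeptide genes Gal (1332 ± 219 TPM) and Calca (203 ± 57.6 TPM) were highest, and Tac1, Calcb and Adcyap1 lay between 27.9 and 32.3 TPM. Prdm12, a regulator of nociceptor fate, reached 19.4 ± 7.78 TPM and the heat-gated channel gene Trpv1 6.66 ± 2.91 TPM. Genes of non-peptidergic nociceptors and C-fibre mechanoreceptors were uneven: 9 of 16 reached 1 TPM and the median was 1.07 ± 0.473 TPM. The ATP receptor gene P2rx3 (359 ± 67.4 TPM), Th (60.9 ± 13.9 TPM) and Scn10a (45.2 ± 18.7 TPM) led this list, while Trpa1, Mrgpra3 and Mrgprb4 had at most 4 counts in a library.

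Myelinated mechanoreceptor and proprioceptor genes were also present. The mechanoreceptor list had a median of 16.0 ± 4.59 TPM, led by Cntnap2 (46.5 ± 7.30 TPM), Shox2 (38.3 ± 4.92 TPM) and the touch channel gene Piezo2 (32.5 ± 3.10 TPM). Calb1 was uneven, at 36.9 TPM in A, 50.2 in B and 9.63 in D. Maf stood at 24.2 ± 12.3 TPM against 0.523 ± 0.311 TPM for Mafa, and Piezo2 contrasted with Piezo1 at 0.0864 ± 0.00779 TPM. Neither ratio was computed, since Mafa and Piezo1 had under 10 counts in a library. The proprioceptor list (median 12.9 ± 0.798 TPM) was led by Pou4f3 (137 ± 18.7 TPM) and Pvalb (mean 66.4 TPM). Its median is the value of Ntrk3, as is that of the neurotrophin receptors. Of its 9 members, 3 are also in other lists, among them Pou4f3 in the sensory neuron list. Runx3, a regulator of proprioceptors, exceeded Runx1, a regulator of nociceptors, 2.76-fold (log2 Runx1/Runx3 -1.47 ± 0.28, 3 of 3 libraries, exact p = 0.25). As CPM, without length correction, the log2 ratio was -0.22.

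Among channels that sense force or acid, Asic3 was highest (74.0 ± 19.7 TPM), followed by Tmem63b, Tmem150c and Asic1, and the list median was 24.2 ± 1.31 TPM. Sodium channel genes had a median of 6.36 ± 0.640 TPM. Scn3b (191 ± 92.3 TPM) and Scn9a (102 ± 46.2 TPM) were highest. The ratio of Scn9a to Scn10a was not stable (log2 1.15 ± 1.39, exact p = 0.5), at 1.33 in A, -0.32 in B and 2.44 in D, and its mean was 1.88 without B and 0.50 without D. Axon guidance receptors had a median of 4.19 ± 0.702 TPM, with Nrp1 (284 ± 91.6 TPM), L1cam (117 ± 49.2 TPM) and Cntn1 (70.8 ± 19.8 TPM) at the top and no counts of Robo3.

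Hox genes, which mark position along the body axis, were described because the ganglia came from lower thoracic to sacral levels. Paralog groups 7, 9 and 10 held most of the expression, with summed levels of 90.2 ± 7.40, 56.4 ± 7.83 and 82.7 ± 12.4 TPM. Hoxa7 (48.1 ± 6.83 TPM), Hoxb7 (42.1 ± 11.7 TPM), Hoxa10 (37.1 ± 4.81 TPM), Hoxc10 (30.1 ± 5.15 TPM) and Hoxb9 (25.9 ± 4.78 TPM) were the highest genes. Group 8 summed to 15.6 ± 0.508 TPM and group 11 to 6.23 ± 0.940 TPM. Group 13 summed to 0.669 ± 0.292 TPM, with no counts of Hoxa13 or Hoxd13. Of all 39 Hox genes, 21 reached 1 TPM, with a list median of 1.46 ± 0.203 TPM.

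**Figure D3:**
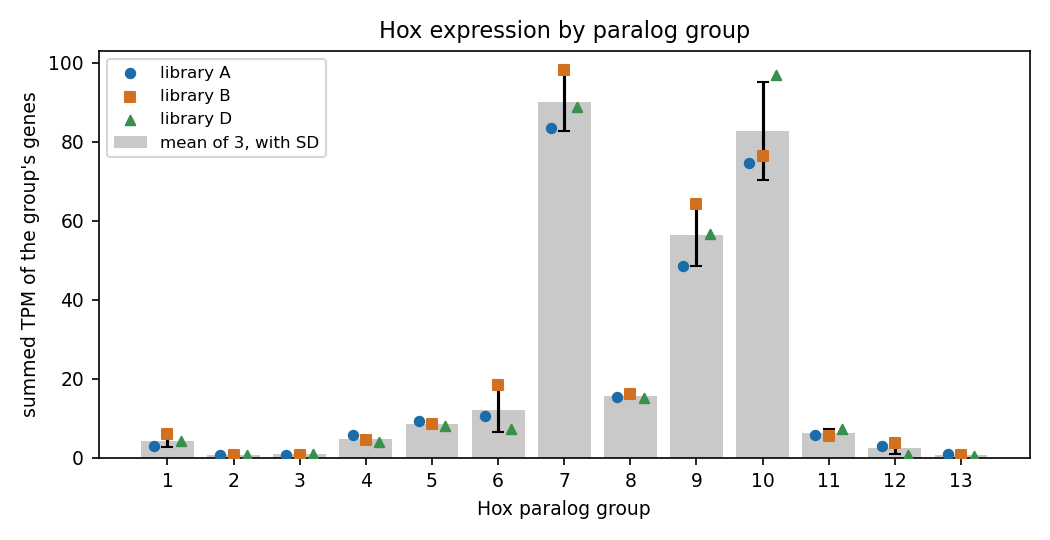
Summed TPM (y axis) of the Hox genes in each paralog group (x axis). Bars are means of 3 libraries with SD, and symbols are libraries A, B and D. Groups 7 and 10 were highest, and group 13 stayed below 1 TPM in each library.

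Proliferation and stress genes were low beside the neuronal list, but most of them were expressed. Cell cycle genes had a median of 4.61 ± 1.06 TPM, with Pcna (27.4 ± 2.27 TPM) and Rrm2 (17.9 ± 4.97 TPM) highest. Of these genes, 11 of 12 reached 1 TPM, all but Mki67 (0.364 ± 0.211 TPM). Immediate early and stress genes had a median of 5.78 ± 2.25 TPM, led by Fos (71.1 ± 21.6 TPM) and Jun (37.4 ± 4.93 TPM), and 11 of 13 reached 1 TPM. Among random lists of the same size, the mean log2 levels of the 2 lists stood at percentiles 85.1 and 88.5.

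Sex-linked genes were set beside the embryos that the labels list. Xist, transcribed from the inactive X of females, reached 29.7 CPM in A, 28.3 in B and 21.2 in D. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together reached 101, 35.2 and 90.7 CPM. The log2 ratio of Xist to their sum was -1.76 in A, -0.31 in B and -2.10 in D, where 2 of 5, 4 of 6 and 1 of 4 embryos were female. The median of the 5 sex-linked genes was 4.13 ± 1.38 TPM. The order of the ratios matched the order of female shares in all 3 pairs of libraries, and in 2 pairs when Uty or Kdm5d alone was used. Neither Xist nor the Y-linked sum alone followed the labels, since both were highest in A. No correlation was computed from 3 libraries.

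The last comparisons asked where the 3 libraries differed. Between them, 24 of 13530 genes varied by more than other genes of their level (edgeR goodness-of-fit, Benjamini-Hochberg adjusted), with edgeR's common biological coefficient of variation of 30.3%, and 827 genes had an unadjusted p under 0.05. With so many genes tested, many pass an unadjusted threshold without varying further, so the 827 are not added calls. Tmem163, a zinc transporter gene, differed most, with 12491 counts in A against 624 in B and 1334 in D (20.8-fold range, adjusted p = 4.6e-12). Each call was assigned to the library with the largest absolute log2 difference from the mean of the other 2. By this rule, 2 were high in A (Tmem163 and the imprinted RNA Meg3), 4 were high and 6 low in B, and 3 were high and 9 low in D. Some lay far out in a further library as well, so the split is not sharp. Malat1 lay at -2.33 in B and 2.13 in D, and Meg3 at 2.74 in A and -2.29 in B. H2afx lay at -2.46 in D and 2.05 in B, and Sf3a2 at 2.22 in B and -1.98 in D. High in B were Col1a1 (9.62-fold range, adjusted p = 5.8e-05), Jph3, Sf3a2 and Junb. Low in B were Malat1 (13350 counts against 41335 in A and 135335 in D, adjusted p = 0.0061), Kcnq1ot1 (antisense to Kcnq1, so its reads may include that gene's), Atrx, Akap9 and Gm26871 among others. Pgls, an enzyme gene of the pentose phosphate pathway, was low in D (10.8-fold range, adjusted p = 0.00036), as were Mrps34, Malsu1, Rbfa, H2afx, Med9, Tmem132a and Pgam5. The adult beta-globin genes Hbb-bs and Hbb-bt, near-identical copies whose reads may not be separable, were high in D (adjusted p = 0.022 and 0.027). These edgeR calls were lost with the length trend removed (adjusted p = 0.17 and 0.29, log2 difference of Hbb-bs in D 1.77 against 2.41 and of Hbb-bt 1.63 against 2.38) and with library totals alone (adjusted p = 0.055 and 0.068), where the differences stayed at 2.29 and 2.26. The length correction also ended the calls of Kcnq1ot1 in B (log2 difference -1.74 against -2.69) and of mt-Tc, a mitochondrial tRNA gene high in D (1.20 against 2.53). With the GC trend removed, 6 calls passed the threshold no longer although most of each difference stayed. In B these were Atrx (-2.19 against -2.50), Gm26871 (-2.38 against -2.93), Junb (2.33 against 2.78), Jph3 (1.81 against 2.19) and Sf3a2 (1.78 against 2.22), and in D H2afx (-2.35 against -2.46). Akap9 and Atrx missed the threshold with library totals alone (-2.37 and -2.41) and with a common dispersion (-2.46 and -2.50, unmoved), Gm26871 with library totals alone (-2.84) and Akap9 with no filter (-2.45). The count of calls was 7 without A, 2 without B and 27 without D, and with trends in gene length removed it was 55. Across genes, differences from the other libraries correlated with GC content in B (Pearson r 0.373) and inversely in A (-0.254), and with gene length in A (0.347) and inversely in D (-0.313).

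Whole lists shifted between libraries too. Of 78 list medians, 19 lay outside the central 95% of matched random lists. For lists of unrelated genes, 3.9 would be expected. Members of a list may vary together, which random lists do not reproduce, and a list's values in A, B and D are tied to each other. The value of 3.9 is therefore no chance rate for these lists, and the count of 19 only describes the libraries. Glial genes were lower in A (median log2 difference from the other libraries -0.81, 12 of 15 members) and higher in B (0.64, 13 of 15). Mesenchyme and pericyte genes lay at -0.98 in A (10 of 12 lower) and 0.82 in B (10 of 12 higher), but A did not lie below D alone (0.07). Erythroid genes were lower in B (-1.26, 10 of 10; -0.47 against A alone, within the random range) and higher in D (1.49, 9 of 10). Macrophage genes were higher in A (0.93, 9 of 10; 0.63 against B alone, within the random range). Peptidergic nociceptor genes were lower in A (-0.71, 7 of 8), with Prdm12 at -1.09 and Calca at -0.92, and higher in D (0.48, 5 of 8; 0.06 against B alone, within the random range). Sympathetic neuron genes lay at 0.52 in A and -0.64 in D, but at 0.24 in A against B alone and -0.45 in D against B alone, both within the random range. In B, cartilage genes lay at 0.72, cell cycle genes at 0.41 and immediate early and stress genes at 0.38, each within the random range against D alone (0.54, 0.44 and 0.017). Sodium channel genes lay at 0.43 in B with 7 of 13 higher, but at -0.26 with members of at least 1 TPM. In A, skeletal muscle genes lay at -0.68 and Hox genes at -0.27, each within the random range against B alone (-0.52 and -0.12). Of the 9 muscle genes 2 reached 1 TPM, and of the 6 cartilage genes 1 did. The muscle and cartilage shifts therefore rest mostly on genes with few counts. Sex-linked genes lay at 1.03 in A (0.39 against D alone, within the random range) and -1.51 in B. The sensory neuron and RET and GFRA receptor lists stayed inside the random range in every library. Random lists were matched on level and not on gene length, and the shifts were not repeated with the length trend removed. The shortest 10% of genes lay at a median of -0.44 in A and 0.62 in D. Whether length contributes to shifts of lists with short genes, such as Gal (712 bases) and Hbb-bs (863 bases), was not tested.

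**Figure D4:**
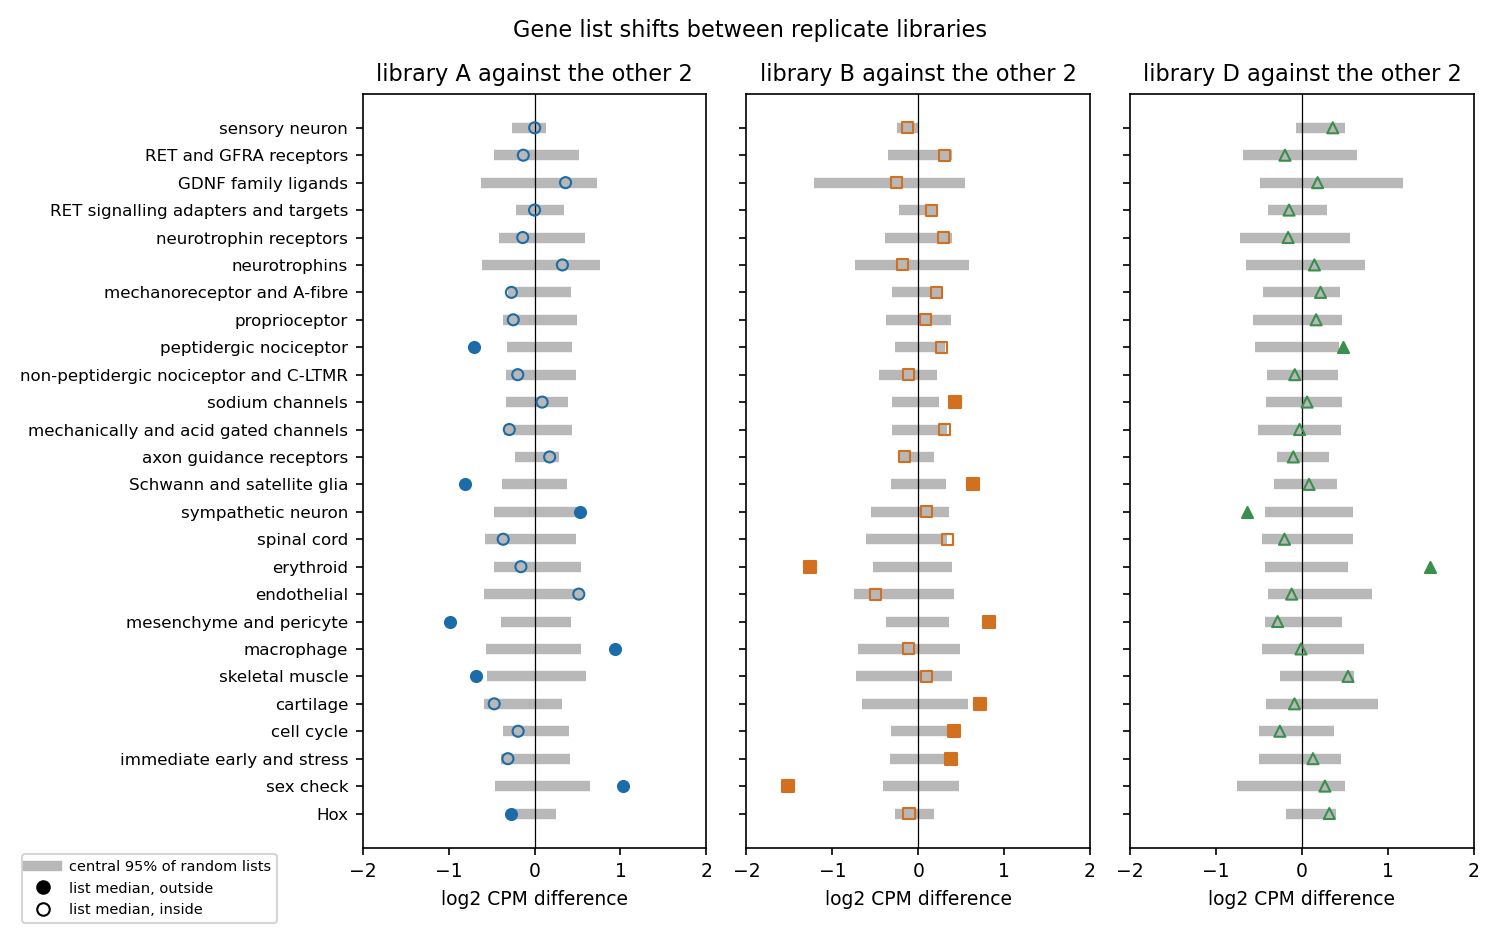
Median log2 CPM difference (x axis) of each of 26 gene lists (y axis) in libraries A, B and D against the mean of the other 2. Symbols are list medians, filled where outside the central 95% of 10000 matched random lists (grey bars). Erythroid genes lay highest in D (1.49) and glial and mesenchyme genes lay low in A and high in B.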

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

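The removal of GC and length trends, and the list shifts against each other library alone, were chosen only after the results were seen. The sensory neuron list stayed above all 9 other-cell lists in every library as CPM, with members of at least 1 TPM and with both mean log2 summaries. The size of the gap depended on the summary, since many members of the other lists were near 0. As CPM, the log2 ratio of sensory neuron genes was 5.04 to glia, 8.34 to sympathetic, 6.54 to erythroid, 6.36 to mesenchyme and 8.65 to macrophage genes. With members of at least 1 TPM it was 3.03 to glia, 3.18 to sympathetic, 5.25 to endothelial, 4.65 to mesenchyme, 5.67 to macrophage, 3.43 to muscle and 6.68 to cartilage genes. With the mean of log2(TPM + 0.1) it was 6.98 to sympathetic, 5.24 to erythroid and 8.74 to muscle genes. With log2(TPM + 1) it was 5.80 to sympathetic, 4.54 to erythroid, 6.73 to endothelial, 5.99 to macrophage, 6.61 to muscle and 7.10 to cartilage genes. Without D the ratio to erythroid genes was 4.06, and without A that to muscle genes was 10.75.

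Gene ratios rested on the length correction, since CPM leaves it out. As CPM, the log2 ratio was 0.59 for Gfra1/Gfra2, -1.31 for Gfra2/Gfra3, -0.72 for Gfra1/Gfra3, 0.60 for Ret/Gfra2, -0.71 for Ret/Gfra3, 1.75 for Ret/Ntrk2, 2.69 for Ret/Ntrk3 and -0.22 for Runx1/Runx3, and Ntrk2/Ntrk3 turned to 0.94. With a pseudocount of 1, Runx1/Runx3 was -0.94. Scn9a/Scn10a was 1.88 without B and 0.50 without D.

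The 24 varying genes became 37 with a mean CPM of at least 1, 55 with length trends removed and 59 with GC and length trends removed, of which 24, 20 and 20 were shared. Leaving out a library gave 2 to 27. DESeq2 dispersion outliers numbered 18, of which 5 were shared. The cause was not tested. Among the list shifts, sodium channels in B turned to -0.26 with members of at least 1 TPM and to -0.44 with the GC trend removed, and mesenchyme genes in A ranged from -1.46 against B alone to 0.069 against D alone. Of the other shifts under an alternative, 85 stayed outside the random range on the same side and 22 did not. Apart from comparisons with single libraries, those lost were sympathetic genes in A and D and stress genes in B with the GC trend removed, sympathetic genes in A, stress genes in B and Hox genes in A with a prior count of 0.5, and sympathetic genes in D and stress genes in B with members of at least 1 TPM. The muscle and cartilage lists had too few members of at least 1 TPM for their shifts to be repeated with those members alone. The order of sex gene ratios matched in 2 pairs with Uty and 2 with Kdm5d. Genes with few counts were limited by depth. No paired analysis was possible because there is 1 group.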

Other observations

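The test of the GC trend for the genes low in library B, the comparison of blood RNA amounts, the nuclear RNA value with the GC trend removed and the values of both lists against single libraries were chosen only after the results were seen.

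Transmitter genes of autonomic and motor neurons were unevenly expressed. Among sympathetic genes, Th (60.9 ± 13.9 TPM, also a marker of C-fibre mechanoreceptors), the vesicular monoamine transporter gene Slc18a2 (23.4 ± 6.49 TPM) and the nicotinic receptor gene Chrna3 (17.6 ± 6.68 TPM) were expressed. Dbh, which makes noradrenaline, reached 2.47 ± 1.35 TPM, and the noradrenaline transporter gene Slc6a2 had at most 4 counts. Of the cholinergic genes, Slc5a7 reached 6.13 ± 2.73 TPM while Chat had at most 3 counts. Slc18a3 (1.13 ± 0.772 TPM) lies within the Chat locus, and reads of overlapping genes were not separable.

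Markers of other cell types were uneven within their lists. Sparc, a matrix protein gene, reached 159 ± 77.4 TPM against 11.5 ± 14.7 TPM for Col1a1. The macrophage list was led by Fcer1g (17.8 ± 0.508 TPM) and C1qb (8.09 ± 3.12 TPM). Of the muscle genes, Acta1 (19.8 ± 4.03 TPM) and Tnnt1 (8.67 ± 1.96 TPM) were above 1 TPM. Egfl7 (5.99 ± 2.40 TPM) and Pecam1 (2.40 ± 0.769 TPM) were so among endothelial genes, and Col2a1 (1.65 ± 0.984 TPM) among cartilage genes.

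Hemoglobin transcripts differed in kind as well as amount. Embryonic globins (Hbb-y, Hba-x and Hbb-bh1) took 54.0% of globin counts in A (exact Clopper-Pearson 95% interval 51.0 to 57.1), 28.5% in B (25.03 to 32.1) and 14.5% in D (13.3 to 15.7), with all globins at 52.3, 31.7 and 122 CPM. The adult genes include near-identical copies, and the treatment of reads with several matches is not given. The shares may therefore be biased in a way that the intervals do not cover. The ratio of embryonic to adult counts spanned 6.95-fold, which argues against different amounts of the same blood RNA as the whole cause, and with the GC trend removed the log2 ratio in A minus D was 2.78 (2.79 before). Earlier embryos in A remain a candidate explanation: progenitor and newborn neuron genes lay at a median of -0.13 in A (30.4th percentile), which met the bound set against it but lay inside the random lists' central 95% range (-0.37 to 0.37), a reading fixed after the value was seen, and it was -0.51 against B alone (below the random range, 7 of 11 lower) and 0.26 against D alone (inside it). Stage therefore stays open, the parents and sex of the pools were not tested, and the EGFP sort is a gate that would remove red cells.

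The 6 genes assigned to B as low held the long noncoding RNAs Malat1, Kcnq1ot1 and Gm26871 and the coding genes Atrx and Akap9. Their median log2 difference of -2.56 (SD 0.21) was -2.34 (SD 0.11) with the GC trend removed, where 4 of 6 were still called. With the length trend removed it was -2.29 (SD 0.42), where 5 of 6 were. Neither trend, averaged over genes, accounts for the whole difference. The average GC trend was small beside it: in B, genes of at most 41.3% GC lay at a median of -0.28. Its removal could therefore not take most of the difference away. All 6 lay between GC percentiles 0.089 and 25.3, and the 4 genes high in B between 93.9 and 99.1. A link to GC content beyond the average trend was not tested and stays open. A smaller share of nuclear-retained RNA in B may contribute to the low noncoding RNAs. For the coding genes Atrx and Akap9 this was not tested. In B, 7 other nuclear-retained RNAs, not called, lay at a median of -0.99. Of these, 7 of 7 were lower, with Pvt1 at only -0.02. With the GC trend removed, their median was -0.76 with 6 of 7 lower. Their list was written once the varying genes were known. The same RNAs lay at 0.74 in A (6 of 7 higher, but 0.53 and 4 of 7 against D alone, within the random range), which adds to that difference, and B lay below D alone (-0.92, 6 of 7, percentile 0.07) and A alone (-0.96, 6 of 7). What would lower that share in B stays open, and no biological explanation was tested.

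The 9 genes assigned to D as low, with Pgls, Mrps34 and Malsu1 among them, had a median log2 difference of -2.72 (SD 0.29). It was -2.60 (SD 0.27) with the GC trend removed, where 8 of 9 were still called, and -2.78 (SD 0.28) with the length trend removed, where 9 of 9 were. The average GC trend in D was small beside these differences: genes of at least 57.6% GC lay at a median of -0.14. Of the 9, H2afx, Tmem132a, Mrps34, Rbfa and Pgls lay between GC percentiles 89.5 and 98.9. The rest lay between 23.1 and 78.2. Longer genes were lower in D (Pearson r -0.313), yet these 9 lay at or below length percentile 54.5. Removal of either trend could therefore not take much of the difference away. The values show only that the average trends do not account for it. Effects of GC content or length on single genes were not tested, and what sets these genes apart in D stays open. No biological explanation was tested, since the design holds 1 group.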
